A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

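Total RNA of Saccharomyces cerevisiae W303-1a was measured on 4 Agilent two-colour expression arrays. Each array held 12512 spots for genes and 536 control spots, and each gene probe was spotted 2 times. Per the labels, stressed cells (1 M sorbitol or 20% glucose, 30 min) and unstressed YPD cells were hybridised on the same array, with 2 biological replicates per stress and the dyes exchanged between replicates. The labels do not describe how replicate cultures were grown apart, nor whether the sorbitol and glucose sets shared an unstressed culture. All 4 arrays came from 1 slide and 1 scan.

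The intensity values (mean spot signal and median local background in Cy3 and Cy5) were extracted by the authors with Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 8.5.1.1 in the submitters' processing notes, and carry no normalization. The processed signals in the same deposited files are intensity values after background subtraction, detrending and dye normalization, per the file headers. The deposited log10 ratios of Cy5 over Cy3 were made by Feature Extraction from the processed signals and served here only to find the scale of the value table. The authors' value table held log2 ratios of stressed over unstressed RNA, as read from slopes of 3.19, -3.19, 3.21 and -3.22 against the log10 ratios, where log2 of 10 is 3.32. How the authors normalized these values is not stated. The spot flags in the deposited files are 0 or 1 per spot.

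Mean signals were background-corrected with limma's normexp (offset 50) against the local background median, and log2 ratios were normalized within each array by loess. Control spots and spots with an outlier flag had weight 0 (195 and 119 outlier spots on the sorbitol arrays, 128 and 263 on the glucose arrays). Both spots of a probe were averaged, the brightest probe stood for each of the 28 genes with more than 1 probe, and ratios were turned to stressed over unstressed. Of 6227 systematic names 49 were left out because their probe was not well above background in enough spots, which left 6178 genes. Of these 5714 were named through the reference gene table and 464 kept the name in the file. The reference served for names only. Probe coordinates came from the array files, and 5106 of the 5597 tested probes with an open reading frame range lay inside it. Among genes named in the text, the probes of AGA2, ALD2, DBP2, DMC1, HXT3, HXT6, HXT7, MPC3, RPL7B, RPS0B and SLT2 did not.

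Median signals, stressed and unstressed, were 6576.2 and 3989.2 on sorbitol replicate 1, 5905.5 and 6353.2 on sorbitol replicate 2, 7709.3 and 4569.4 on glucose replicate 1, and 6447.3 and 5775.1 on glucose replicate 2. The SD of log2 ratios over genes was 1.39, 0.909, 0.997 and 1.13 in the same order.

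Genes were tested with limma (3.58.1, in R 4.3.3, with the data.table package, version 1.17.8): lmFit with 1 coefficient per stress over the 4 arrays (2 residual degrees of freedom), then eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 3.28 degrees of freedom. The difference was the glucose coefficient minus the sorbitol coefficient. A set of 25 gene lists was fixed before the data were examined, as were all comparisons and most alternatives, and was tested with camera (preset correlation 0.01, adjusted over the 25 lists within a comparison), with camera using an estimated correlation, and with fry. Camera with an estimated correlation and fry rest on the 2 residual degrees of freedom. A list that misses the threshold there is thus not shown to be unchanged. The 7 genes missing a value on an array were left out of the list tests. Older symbols were matched through the reference, and in the cell wall list MLP1 matched the gene of a nuclear pore protein rather than the kinase that shares this alias. The list named for RNA polymerase I and III subunits also held RRN genes, which encode initiation factors of polymerase I. Some genes belong to more than 1 list, so results of such lists are not independent. The general stress list shares genes with those of trehalose and glycogen, chaperones, oxidative defence, glycolysis, glycerol and the cell wall. Counts of list members were also adjusted over the list alone. No other splits of the samples were counted, since each group held 2 arrays.

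For each comparison the genes named were the 10 largest rises and 10 largest falls among passing genes whose arrays agreed in sign and that had a gene symbol and signal above background, or, where fewer passed, the next by size, given as not passing. For the difference, agreement meant that both glucose arrays lay on the same side of both sorbitol arrays. Up to 2 members at either end of a list were also named, and 12 genes were always given. Genes outside that rule are said to have been picked after their values were seen.

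The procedure was tested on simulated data with 6178 genes and the same design. Of genes changed 2-fold, 40.3% were called in sorbitol, 37.3% in glucose and 21.4% in the difference, of genes changed 4-fold 100%, 97.0% and 91.4%, and of genes changed 16-fold 100% in each. Unchanged genes made up 10 of 170 calls in sorbitol, 10 of 166 in glucose and 14 of 290 in the difference, and 0 of 75 tests of lists without a change passed. Noise was drawn independently for each gene, with the same spread in both stresses. In the measured data the estimated correlation within lists was 0.063 (histones and S phase) to 0.944 (ribosome biogenesis). The simulation thus cannot show how often camera calls an unchanged list of correlated genes, nor what share of measured differences is found.

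The alternatives tried were Agilent's processed signals, no background subtraction, normexp offset 0, median centring in place of loess, quantile normalization of average intensities between arrays, no filter on dim probes, a filter on all arrays, keeping outlier spots, averaging probes, a replicate block, an intensity trend with a robust prior, each stress on its own 2 arrays, a 2-fold minimum, the authors' value table, and leaving out each array. Scaling of the arrays to the same median absolute log ratio and centring on the E1A control spots were added after the data had been seen. That centring added the same constant to both arrays of a stress, so the spread of the E1A spots between arrays did not enter the tests. With an array left out, the lone array of its stress had no measured spread, and the spread came from the other pair.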

Results

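Transcript levels were measured in exponentially growing cultures of Saccharomyces cerevisiae W303-1a, a haploid laboratory strain of budding yeast, at an OD600 of 0.8. Cells were held for 30 min in rich medium made hyperosmotic with 20% glucose or with 1 M sorbitol, a sugar alcohol. Unstressed cells in standard YPD medium served as the control. Each of the 4 two-colour Agilent arrays set total RNA of stressed cells against RNA of unstressed cells, with 2 arrays per stress that the labels call biological replicates. In both stresses the stressed RNA carried Cy5 in replicate 1 and Cy3 in replicate 2. The labels do not say whether the unstressed cultures of both sets were shared. Per array and channel, 95.7% to 99.4% of the 6256 probes were well above background, no spot was saturated, and 6178 genes were tested. The number of arrays limits the precision of every value. Log2 changes are stressed over unstressed, with the standard error (SE) of the limma fit and n = 2 arrays per stress, and a value in brackets after a gene is its log2 change. That fit pools the spread of both stresses, so the SE does not measure the spread of either pair of arrays. For HSP12 the SD over the pair was 1.81 in sorbitol and 0.89 in glucose, and for GPP2 1.22 and 1.42, with the same SE in both stresses. Through loess, all are relative to genes of similar average intensity on the same array. Only with median centring are they relative to the median gene. Against 10 control probes that detect E1A RNA, the median gene lay at -1.36 (log2) in sorbitol and at 0.48 in 20% glucose, and the changes below do not include that shift. Coordinates are those of the array probes on the sacCer1 build.

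The first comparison asked which genes 1 M sorbitol changed. The largest rise was in HSP12 (YFL014W, chromosome VI, 107305 to 107364, inside the open reading frame), which encodes a small membrane-associated heat shock protein, with a log2 change of 8.78 ± 0.64 (limma, adjusted p = 0.00423). STL1 (YDR536W, chromosome IV, 1509632 to 1509691), a glycerol-proton symporter gene, rose by 7.58 ± 0.46, measured against an unstressed signal that was well above background on only 1 of the 2 sorbitol arrays. GPP2 and GPD1 (YDL022W, chromosome IV, 412899 to 412958), which encode enzymes of glycerol synthesis, rose by 6.05 ± 0.60 and 5.22 ± 0.69. MPC3, DDR2, HXT5, ALD3, FMP45, RGI2 and PRR2 rose by 5.93 (PRR2) to 7.25 (MPC3). The falls were smaller, led by BSC1 at -3.39 ± 0.33 and the polyamine exporter gene TPO2 at -3.29 ± 0.32. PRM7, RRP5, SYO1, MNN1, PUS7, RPA135, UTP20 and KRE33 fell, with log2 changes of -3.22 (PRM7) to -2.68 (KRE33). The catalase gene CTT1 rose by 5.60 ± 0.44, the methylglyoxal reductase gene GRE2 by 4.40 ± 0.49, the sodium pump gene ENA1 by 2.02 ± 0.36, the glucose transporter gene HXT1 by 2.71 ± 0.31 and HOR7 by 3.53 ± 0.92. HXT3, the phosphate transporter gene PHO84 and the sorbitol dehydrogenase gene SOR1 did not pass the test, with log2 changes of -0.65, -1.69 and -0.29. With median centring in place of loess, HXT1 and HOR7 no longer passed (adjusted p = 0.0569 and 0.225) and SOR1 lay at 0.016, while HXT3 (-1.34) and PHO84 (-2.05) passed, downward (adjusted p = 0.0345 and 0.0295). PHO84 also passed with the authors' value table (adjusted p = 0.0473). HXT3 and PHO84 lay at -1.22 and -2.75 without sorbitol replicate 2, but at -0.073 and -0.64 without replicate 1. HOR7 lay at 1.56 without sorbitol replicate 1 and at 5.49 without replicate 2. Without replicate 1, ENA1 lay at 1.31, and PRM7, RRP5, MNN1, PUS7, UTP20, RPA135 and SYO1 at -2.09 (PRM7) to -1.57 (SYO1). Without either glucose array, where the spread came from the sorbitol pair alone, no gene passed (adjusted p = 0.0513 for HSP12).

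Of 40 general stress genes, targets of the transcription factors Msn2 and Msn4, 39 rose in sorbitol (40 adjusted over the list alone) and ALD2 (0.83) did not pass. Their median was 4.03, with an adjusted p of 8.69e-15 by camera and an adjusted p of 0.712 with an estimated correlation. Trehalose and glycogen genes rose in 15 of 20 cases, TSL1 (3.67) and UGP1 (3.06) the most, and 5 did not pass (16 rose and 1 fell, adjusted over the list alone). This median was 2.05 (adjusted p = 8.32e-05, or adjusted p = 0.712 with an estimated correlation). Among 27 glucose-repressed carbon genes 18 rose (20 and 1 fell, adjusted over the list alone), the lactate permease gene JEN1 (3.87) and ALD4 (3.57) the most. The list's median was 1.54 (adjusted p = 6.89e-06, or adjusted p = 0.712 with an estimated correlation). Heat shock chaperone genes rose in 18 of 27 cases, HSP26 (4.70) and SSA4 (4.54) the most (19 rose and 1 fell, adjusted over the list alone). For these the median was 1.39 (adjusted p = 2.75e-05, or adjusted p = 0.712 with an estimated correlation). Glycerol genes rose in 8 of 14 cases and DAK2 (-1.07) fell, the same counts as adjusted over the list alone. Their median of 1.58 had an adjusted p of 0.016, an adjusted p of 0.712 with an estimated correlation, and missed the threshold with the authors' value table (adjusted p = 0.0755) and with median centring (adjusted p = 0.0524). Oxidative defence genes rose in 13 of 32 cases, CTT1 and GND2 (4.23) the most, and 2 fell (15 and 4 adjusted over the list alone). At a median of 0.72 the adjusted p was 0.00669, with an adjusted p of 0.712 with an estimated correlation and of 0.0831 with median centring. Without sorbitol replicate 1 the medians of trehalose and glycogen and of oxidative defence were 1.32 and 0.42, UGP1 lay at 1.78 and ALD4 at 2.31, and without replicate 2 the oxidative defence median was 1.24.

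Genes for making ribosomes were among those that fell in sorbitol. Of 91 ribosome biogenesis genes 51 fell and 40 did not pass (56 fell when adjusted over the list alone), with RRP5 (-3.03) and UTP20 (-2.71) lowest. Their median was -1.52 (camera, adjusted p = 1.68e-12, or adjusted p = 0.712 with an estimated correlation), and it was -0.70 without sorbitol replicate 1 and -2.37 without replicate 2, passing in both. Of 136 cytosolic ribosomal protein genes 43 fell, RPS0B (-2.28) the most, and RPL15B (0.81) rose (38 fell and 1 rose, adjusted over the list alone). This list had a median of -0.79 (adjusted p = 6.81e-10, or adjusted p = 0.712 with an estimated correlation). Among 26 genes of RNA polymerase I and III subunits and initiation factors 9 fell, with RPA135 (-2.71) lowest, and 4 rose, with RPA14 (1.22) highest (12 and 4 adjusted over the list alone). Here the median was -0.82 (adjusted p = 0.0113, or adjusted p = 0.712 with an estimated correlation). Amino acid biosynthesis genes fell in 23 of 62 cases, also when adjusted over the list alone, HIS1 (-2.36) and ASN1 (-2.35) the most. A median of -0.66 gave an adjusted p of 2.75e-05 and an adjusted p of 0.712 with an estimated correlation. In the phosphate regulon 8 of 19 genes fell, among them the polyphosphate synthesis gene VTC3 (-2.58), while PHO92 (4.36), which encodes an RNA-binding protein, and PHM8 (1.57) rose (9 and 2 adjusted over the list alone). The regulon's median was -1.31 (adjusted p = 0.00895, or adjusted p = 0.712 with an estimated correlation). Histone and S phase genes had a median of -0.22, and 8 of 31 fell, the cohesin gene SMC3 (-1.64) the most (3 adjusted over the list alone). Camera gave them an adjusted p of 0.0156, and an adjusted p of 0.712 with an estimated correlation. Without sorbitol replicate 1, whose log2 ratios had an SD of 1.39 over genes against 0.909 in replicate 2, the polymerase list (-0.43, adjusted p = 0.0669) and the phosphate list (-0.53, adjusted p = 0.0548) no longer passed. The amino acid median was then -0.34, and RRP5, UTP20, RPA135 and SMC3 lay at -1.89, -1.66, -1.62 and -1.08. Without sorbitol replicate 2 the polymerase and histone medians were -1.28 and -0.34, and with median centring those of ribosomal proteins and histones were -1.56 and -0.43.

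Rises in sorbitol were also found in 14 of 35 genes of the respiratory chain and ATP synthase, led by CYC7 (4.44), and ATP20 (-1.02) fell. Mitochondrial ribosomal protein genes rose in 21 of 64 cases, led by MRPS17 (2.13), and MRPL44 (-0.69) fell. Of 33 proteasome genes 6 rose, led by their transcriptional activator RPN4 (2.86). Adjusted over the list alone, 14, 21 and 2 genes of these 3 lists rose and 1, 1 and 0 fell. Their medians were 0.74, 0.34 and 0.42 (camera, adjusted p = 0.015, 0.011 and 0.0113, or adjusted p = 0.712 for each with an estimated correlation). None of the 3 passed without sorbitol replicate 1 (adjusted p = 0.289 for each), nor did the first and last with median centring (adjusted p = 0.181 and 0.398). Respiratory chain and proteasome genes had medians of 0.11 and 0.23 without sorbitol replicate 1, where CYC7 lay at 2.61, and the respiratory chain 1.20 without replicate 2. Markers of other kinds of yeast cell, alpha cells and meiotic cells, rose in 12 of 20 cases, also when adjusted over the list alone. Their median was 0.85 (adjusted p = 0.000416, or adjusted p = 0.712 with an estimated correlation). The genes that moved most were DIT2 (2.84), which acts in building the spore wall, and DMC1 (2.76), which acts in meiotic recombination, while the alpha-cell genes SAG1 (0.09) and STE3 (0.31), picked after their values were seen, did not pass.

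The other 9 lists did not pass in sorbitol, with medians of 0.72 for the TCA cycle, 0.67 for glycolysis and fermentation, which turned to -0.39 with median centring, and 0.39 for hexose transporters and sensors. HOG pathway components, which carry the osmotic signal, had a median of -0.0063, the mating response 0.06, sulfur and methionine genes -0.11 and the iron regulon -0.29. Ergosterol synthesis at -0.27 and the cell wall at -0.38 passed, downward, with median centring (adjusted p = 0.00619 for both), and ergosterol synthesis also without sorbitol replicate 2 (adjusted p = 0.0428). Glycolysis passed, upward, with the authors' value table (adjusted p = 0.0319) and without sorbitol replicate 2 (0.00476), glucose replicate 1 (0.0282) or glucose replicate 2 (0.0283). The TCA cycle passed with no filter (0.0497), the authors' table (0.0463), scaled arrays (0.042) and without sorbitol replicate 2 (0.00174) or glucose replicate 1 (0.0498). In all, limma's moderated test over the 4 arrays called 2482 genes, 1406 up and 1076 down, of which 347 rose and 70 fell at least 4-fold. It called 1576 genes without sorbitol replicate 1, and 0 without either glucose array (2484 at an unadjusted p under 0.05), where the spread came from the sorbitol pair alone. Centred on the E1A control spots, 298 genes were called higher and 4755 lower. The same constant was added to both arrays, although the median gene lay at -2.01 on replicate 1 and -0.71 on replicate 2 against these spots. That spread did not enter the test.

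**Figure D1:**
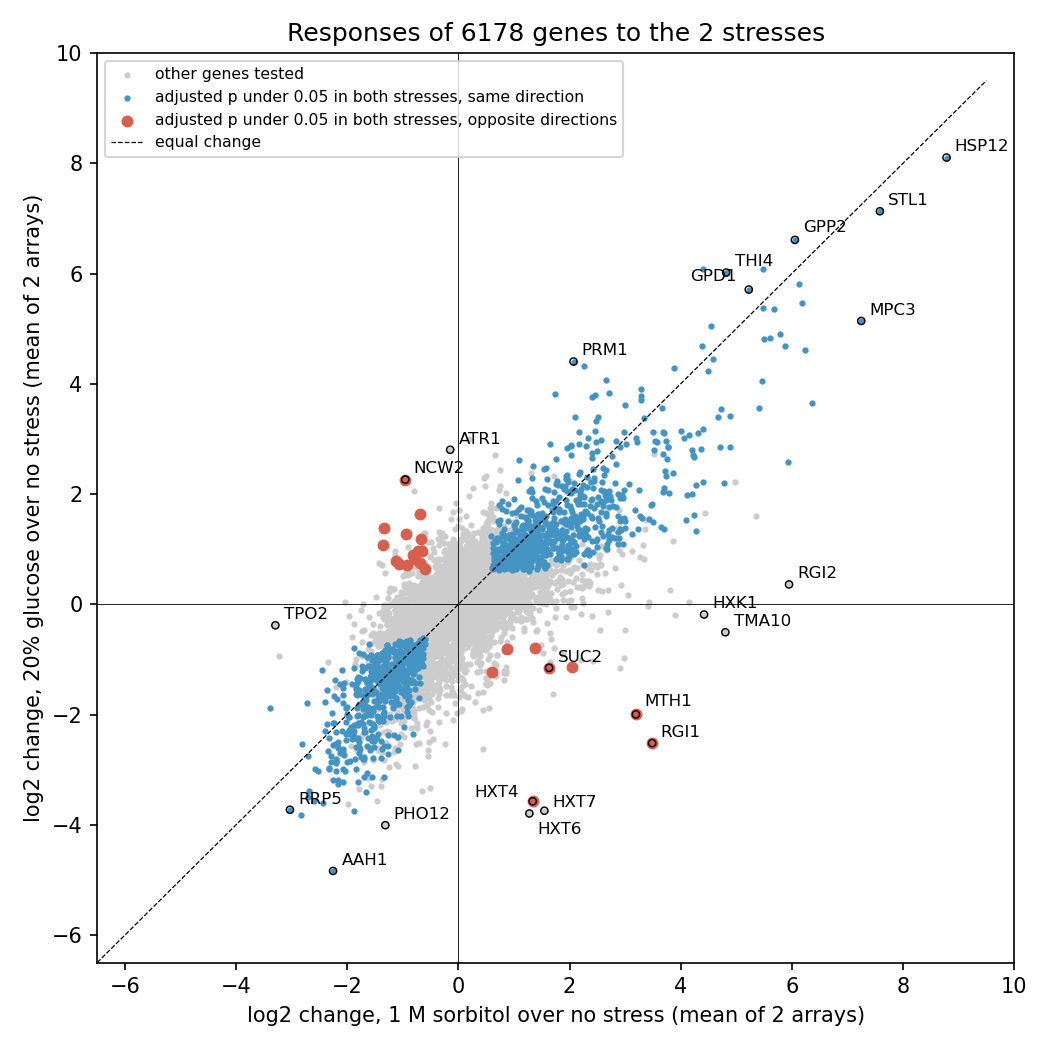
Log2 change in 20% glucose (vertical axis) against log2 change in 1 M sorbitol (horizontal axis) for 6178 genes, each the mean of 2 arrays, with genes called in both stresses in colour. HSP12 and STL1 lie at the upper right near the line of equal change, RGI2 lies at 5.95 in sorbitol and 0.36 in glucose, and the 23 genes called in opposite directions include RGI1 and MTH1 at the lower right and NCW2 at the upper left.

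The second comparison asked which genes 20% glucose changed. HSP12 and STL1 again rose the most, by 8.10 ± 0.64 and 7.13 ± 0.46, and the glycerol synthesis genes GPP2 and GPD1 rose by 6.61 ± 0.60 and 5.71 ± 0.69. GRE2, the transaldolase gene NQM1, the thiamine synthesis gene THI4, FMP45, ALD3 and RTC3 rose by 5.35 (RTC3) to 6.07 (GRE2). The largest fall was in the adenine deaminase gene AAH1 (YNL141W, chromosome XIV, 360384 to 360443), at -4.84 ± 0.45 (limma, adjusted p = 0.0111). HXT4 (YHR092C, chromosome VIII, 287083 to 287107), HXT6 and HXT7, which encode glucose transporters of higher affinity, fell, at -3.57 ± 0.26, -3.79 ± 0.50 and -3.75 ± 0.60. So did the acid phosphatase gene PHO12 (-4.01), SYO1 (-3.82), NOP7 (-3.74), RRP5 (-3.73), URA7 (-3.62) and DBP2 (-3.61). HXT6 and HXT7, and PHO11 and PHO12, are near-identical copies, so a probe of one may take up RNA of the other, and the probes of HXT6 and HXT7 did not lie inside the given open reading frame range. CTT1 rose by 4.83 ± 0.44, ENA1 by 2.87 ± 0.36 and HXT1 by 3.83 ± 0.31, while HXT3 (-1.45) and PHO84 (-2.86) fell. SOR1 (0.64) and HOR7 (2.73) did not pass, but both passed with scaled arrays (adjusted p = 0.0318 and 0.0162), an alternative chosen after seeing the data, and SOR1 with median centring (adjusted p = 0.0287). Without either sorbitol array, where the spread came from the glucose pair alone, both passed as well (adjusted p = 0.0157 for SOR1 and 8.44e-05 for HOR7). Without either glucose array no gene passed (adjusted p = 0.167 for HSP12 without replicate 1 and 0.293 without replicate 2).

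General stress genes rose in 31 of 40 cases in 20% glucose (33 rose and 1 fell, adjusted over the list alone), and the lowest values, of GPH1 (-1.02) and TMA10 (-0.51), did not pass. Their median was 2.54 (camera, adjusted p = 3.07e-10, or adjusted p = 0.814 with an estimated correlation). Of 33 proteasome genes 26 rose (30 adjusted over the list alone), RPN12 (1.91) and PRE4 (1.49) the most. That list's median was 0.96 (adjusted p = 2.60e-09, or adjusted p = 0.814 with an estimated correlation). Heat shock chaperone genes rose in 15 of 27 cases (17 adjusted over the list alone), SSA4 (5.04) and SSA1 (3.15) the most. With a median of 1.17 the adjusted p was 6.38e-07, and the adjusted p with an estimated correlation 0.814. Glycerol genes rose in 7 of 14 cases, while DAK2 (-0.72) and GPD2 (-1.09) fell, the same counts as adjusted over the list alone. A median of 1.60 gave an adjusted p of 0.0165, an adjusted p of 0.814 with an estimated correlation and of 0.0941 with the authors' value table. Oxidative defence genes rose in 16 of 32 cases, the peroxiredoxin gene PRX1 (3.01) among the highest (16 rose and 1 fell, adjusted over the list alone). They had a median of 0.90, an adjusted p of 0.000939, an adjusted p of 0.814 with an estimated correlation, and one of 0.158 with median centring. Among 27 glucose-repressed carbon genes 13 rose, ALD4 (2.94) and the acetate transporter gene ADY2 (2.55) the most, and 3 fell, with the invertase gene SUC2 (-1.15) and the maltose transporter gene MAL11 (-1.06) lowest (14 and 3 adjusted over the list alone). The list's median was 0.95 (adjusted p = 0.00729, or adjusted p = 0.836 with an estimated correlation), and MAL11 lay at -0.67 without glucose replicate 1. With median centring the medians were 0.53 for the proteasome, 0.44 for chaperones, 0.83 for glycerol genes and 0.48 for oxidative defence.

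Ribosome biogenesis genes fell in 78 of 91 cases in glucose (85 adjusted over the list alone), with NOP7 (-3.74) and RRP5 (-3.73) lowest. Their median was -2.35 (camera, adjusted p = 6.82e-21, or adjusted p = 0.814 with an estimated correlation). Of 136 cytosolic ribosomal protein genes 87 fell and 0 rose (100 fell when adjusted over the list alone), with RPL7B (-3.34) and RPS26B (-3.15) lowest. This list had a median of -1.30 (adjusted p = 1.22e-21, or adjusted p = 0.814 with an estimated correlation). It was -0.85 without glucose replicate 2, where RPS26B lay at -1.88, and -2.27 with median centring. Many of its genes have near-identical copies, so a probe may take up RNA of both. Genes of RNA polymerase I and III subunits and initiation factors fell in 13 of 26 cases (16 adjusted over the list alone), RPA190 (-3.57) the most. Here the median was -1.06 (adjusted p = 0.000336, or adjusted p = 0.814 with an estimated correlation). In the phosphate regulon 12 of 19 genes fell, PHO12 and PHO11 (-3.13) the most, and PHO92 (2.82) and PHM8 (1.60) rose, the same counts as adjusted over the list alone. The regulon's median was -1.65 (adjusted p = 0.00112, or adjusted p = 0.814 with an estimated correlation). Amino acid biosynthesis genes fell in 26 of 62 cases, among them LEU9 (-2.59), and 2 rose, among them ILV5 (0.94; 30 and 4 adjusted over the list alone). A median of -0.67, or -1.11 with median centring, gave an adjusted p of 5.06e-05 and an adjusted p of 0.814 with an estimated correlation. Mitochondrial ribosomal protein genes had a median of -0.27, with 8 of 64 lower, RSM26 (-1.20) among them, 2 higher, and 0 in either direction adjusted over the list alone, where 26 had an unadjusted p under 0.05 in limma. Camera gave them an adjusted p of 0.0127, and an adjusted p of 0.838 with an estimated correlation.

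Of 33 cell wall genes 15 rose in glucose, CWP1 (3.70) and SPI1 (3.42) the most, and 3 fell, GAS3 (-2.22) the most (17 and 5 adjusted over the list alone). Their median was 0.52, but -0.11 with median centring (adjusted p = 0.861), 0.84 with the authors' value table and 0.92 without glucose replicate 2. In camera the adjusted p was 0.0168, the adjusted p with an estimated correlation 0.814, that with Agilent's processed signals 0.0656 and that without glucose replicate 1 0.067. Alpha-cell and meiosis markers rose in 8 of 20 cases, also when adjusted over the list alone, DIT2 (1.76) and the meiosis kinase gene IME2 (1.49) the most. Their median was 0.52 (adjusted p = 0.000715, or adjusted p = 0.814 with an estimated correlation).

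The other 11 lists did not pass in glucose, with medians of 0.39 for HOG pathway components, 0.49 for trehalose and glycogen, 0.50 for the TCA cycle, -0.13 for histones and S phase, -0.14 for sulfur and methionine and -0.01 for the iron regulon. Glycolysis and fermentation at 0.29, the respiratory chain at 0.49 and ergosterol synthesis at 0.25 turned to -0.90, -0.01 and -0.24 with median centring. Single arrays left out brought some of these lists past the threshold: glycolysis upward at 0.75 (adjusted p = 0.00894), sulfur and methionine downward at -0.57 (0.000272) and the iron regulon downward at -0.32 (0.048) without glucose replicate 2, and HOG components upward without glucose replicate 1 (0.0237). The respiratory chain passed, upward, without sorbitol replicate 1 (adjusted p = 0.0494) or 2 (0.049). Among the hexose transporters and sensors 5 genes rose, HXT5 (4.62) and HXT1 (3.83) the most, and 6 fell, HXT6 and HXT7 the most, with a median of 0.16, a mean of -0.20 and an upward direction in camera. The mating response had a median of 0.04, a mean of -0.11 and a downward direction in camera. In all, limma called 2081 genes, 1084 up and 997 down, of which 169 rose and 207 fell at least 4-fold. It called 3214 genes without either sorbitol array and 0 without either glucose array (1524 at an unadjusted p under 0.05 without replicate 1 and 1008 without replicate 2), where the spread came from the sorbitol pair alone. Centred on the E1A control spots, 2533 genes were called higher and 499 lower. Here too both arrays received the same constant, although the median gene lay at -0.04 on glucose replicate 1 and 0.99 on replicate 2 against these spots.

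**Figure D2:**
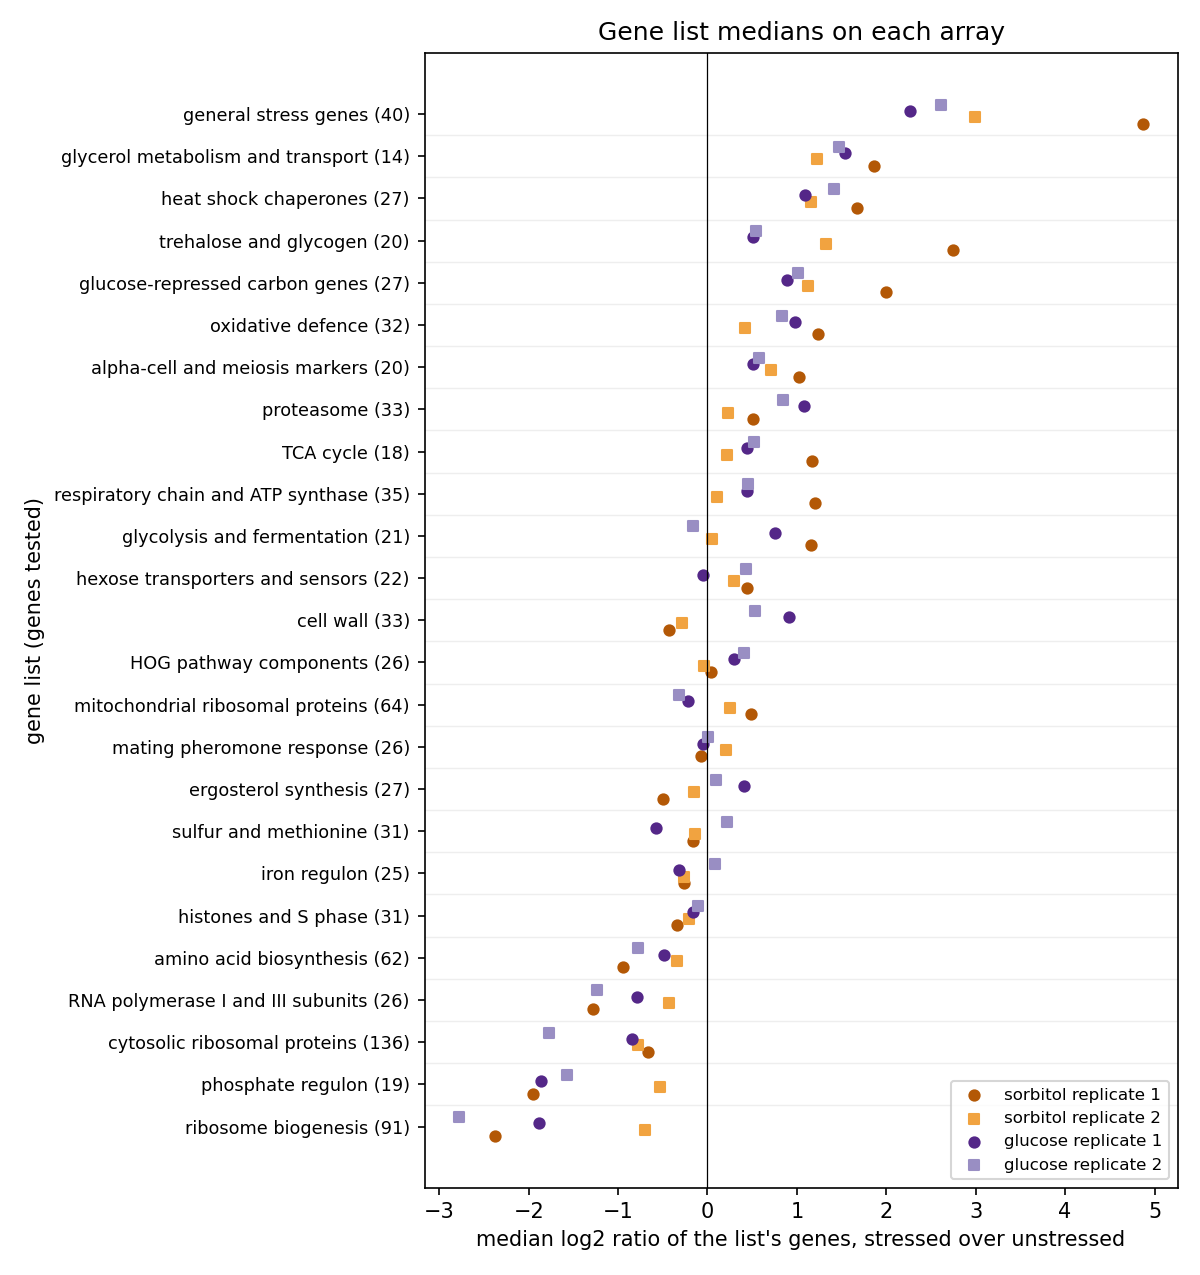
Median log2 ratio (stressed over unstressed, horizontal axis) of the genes of each of 25 lists on each of the 4 arrays, with the number of genes tested in brackets. General stress genes lie highest on sorbitol replicate 1, at 4.87, and lowest on glucose replicate 1, at 2.26, and cell wall genes lie at -0.43 and -0.29 in sorbitol and at 0.92 and 0.53 in glucose, where their median turned to -0.11 with median centring.

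Sorbitol and glucose moved many of the same genes. HSP12, STL1, GPP2, GPD1, CTT1, GRE2 and ENA1 rose in both stresses, and RRP5 and SYO1 fell in both. In the same direction 1250 genes were called, 728 up and 522 down, where independent lists of these sizes would share 246.7 and 173.6. Across the 6178 genes, which are not independent replicates, the mean responses had a Pearson's r of 0.764 and a Spearman's rho of 0.737. Single pairs of a sorbitol and a glucose array gave r of 0.623 to 0.764, while replicates correlated at 0.860 in sorbitol and 0.906 in glucose. The labels leave open whether both sets used the same unstressed cultures, so part of the overlap may come from a shared control. The shared count was 2136 without sorbitol replicate 2, 0 without either glucose array, where limma called no gene in either stress, and 758 when centred on the E1A spots, and r was 0.674 without sorbitol replicate 1.

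The last comparison set the response to 20% glucose against that to sorbitol, the contrast that the series title names. Since no glucose content was recorded for the sorbitol medium, the added compound and the glucose level cannot be told apart in it. The glucose transporter genes HXT4, HXT6 and HXT7 and the genes RGI1 and RGI2 lay among the lowest in glucose relative to sorbitol, and the cell wall genes NCW2 and CRH1 among the highest. RGI1 (YER067W, chromosome V, 292490 to 292549), a gene induced during respiratory growth, had a log2 difference of -6.00 ± 0.94. MTH1 (YDR277C, chromosome IV, 1014553 to 1014612), a repressor of hexose transporter genes, differed by -5.19 ± 0.51, HXT4 by -4.91 ± 0.37, HXT7 by -5.29 ± 0.86 and HXT6 by -5.07 ± 0.71. RGI2, TMA10, the hexokinase gene HXK1, EGO4 and MRK1 lay at -5.59 (RGI2) to -4.10 (MRK1). In the other direction, the cell wall genes NCW2 and CRH1 differed by 3.22 ± 0.32 and 2.86 ± 0.35, the multidrug transporter gene ATR1 by 2.95 ± 0.25 and TPO2 by 2.91 ± 0.45. PUN1, the yapsin protease gene YPS3, TOG1, the chitin synthase gene CHS1, PRM1 and PRM7 lay at 2.28 (PRM7) to 2.80 (PUN1). PRM7 lay at 1.15 and TMA10 at -3.33 without sorbitol replicate 1, and PRM7 at 3.41 without replicate 2. None of these passed over the 4 arrays: limma called 0 genes, with a lowest adjusted p of 0.126, although 1251 genes had an unadjusted p under 0.05 where chance gives 308.9. The count was 56 (17 higher, 39 lower) with the 4 arrays scaled to the same median absolute log ratio, an alternative chosen after seeing the data. Without 1 sorbitol array the sorbitol response rests on 1 array and the spread on the glucose pair alone. For single genes, only effect sizes of the difference are thus given for those fits. Centred on the E1A spots the count was 5241 (5219 higher, 22 lower), where the spread of these spots between arrays did not enter the test. The median gene lay at -0.10. Of the 12 genes given in every comparison, GPD1, GPP2, STL1, HSP12, CTT1, ENA1, HXT1, HXT3, SOR1 and HOR7 lay between PHO84 (-1.16) and GRE2 (1.68), and HXT1 differed by 1.12 ± 0.43. The glucose response of HXT1 was 3.31 without glucose replicate 1 and 4.34 without replicate 2, against 2.71 in sorbitol. Without sorbitol replicate 1, the differences were 2.57 for GRE2, 1.56 for ENA1, 1.16 for SOR1, -2.22 for PHO84 and -1.38 for HXT3. STL1 (0.21), HSP12 (0.60), CTT1 (0.15) and HOR7 (1.17) then lay above 0, as did STL1 without glucose replicate 2 (0.24). Without sorbitol replicate 2, HSP12 lay at -1.96, CTT1 at -1.70 and HOR7 at -2.77. GPD1 (-0.67) and GPP2 (-0.31) then lay below 0, as they did without glucose replicate 1 (-0.52 and -0.45). The 20 genes named above kept their directions without either sorbitol array, which the naming rule fixed in advance. The sorbitol response on replicate 1 was 5.29 for GRE2, 2.72 for ENA1, -0.06 for SOR1, -2.75 for PHO84 and -1.22 for HXT3. Glucose means were 6.07, 2.87, 0.64, -2.86 and -1.45 in the same order, so these differences were smaller without sorbitol replicate 2.

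**Figure D3:**
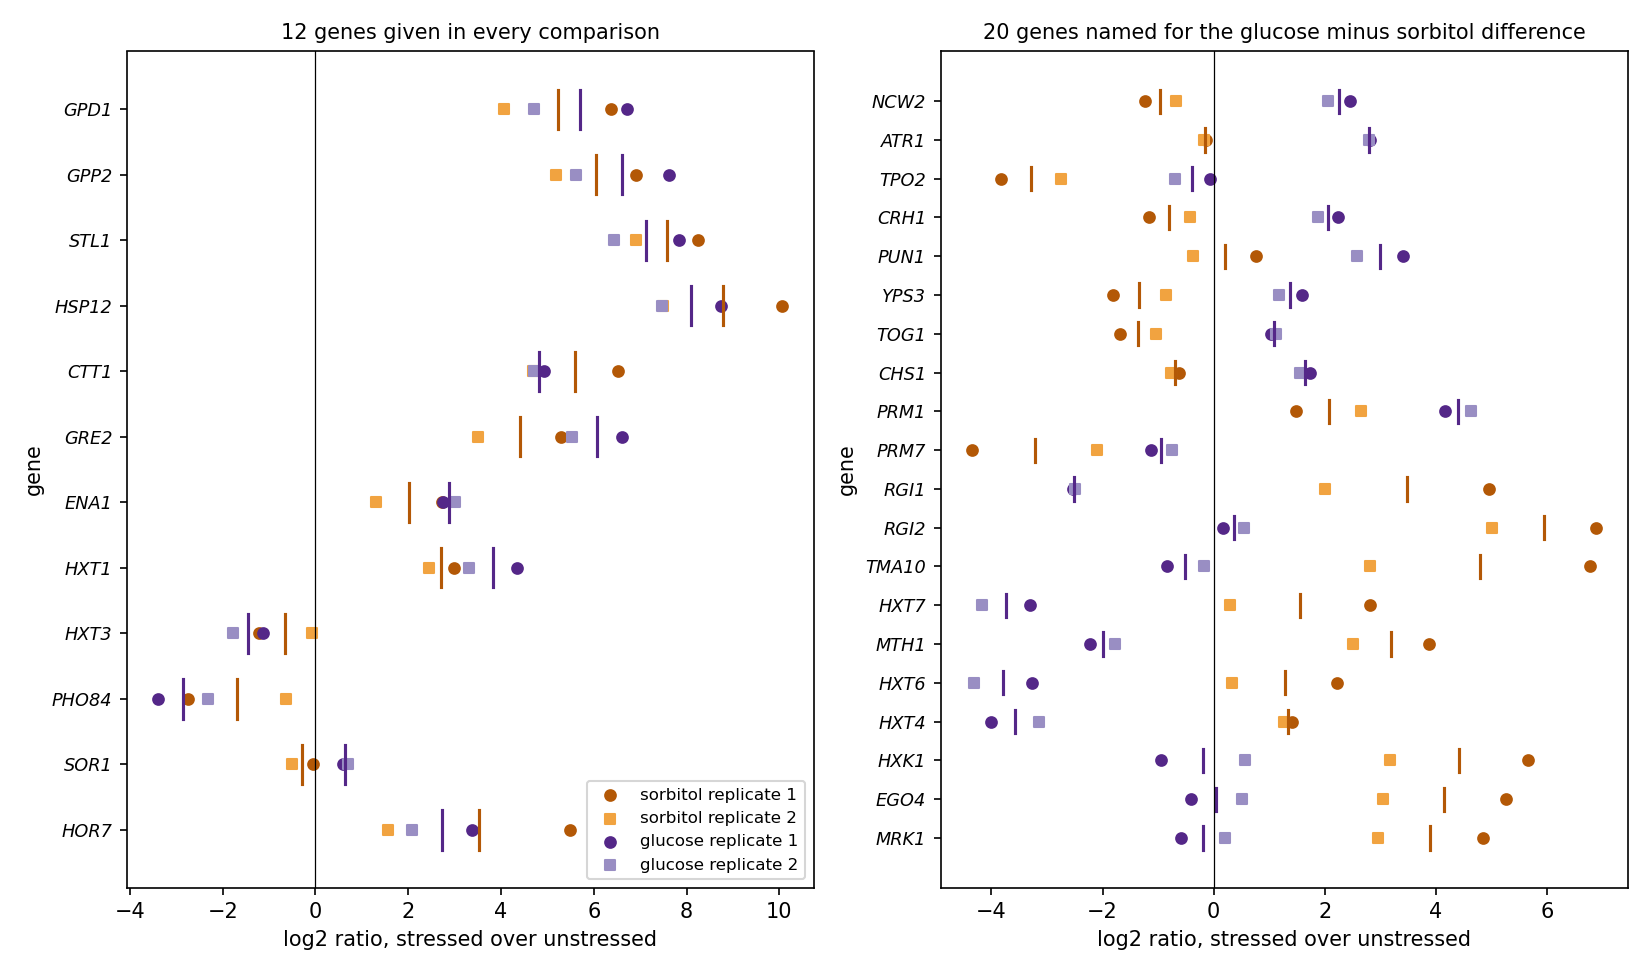
Log2 ratio (stressed over unstressed, horizontal axis) on each of the 4 arrays for the 12 genes given in every comparison and the 20 named for the difference, with vertical bars at the mean of each stress. STL1 lies between 6.43 and 8.25 on all arrays, whereas HXT4 lies at 1.41 and 1.26 in sorbitol and at -4.01 and -3.14 in glucose.

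Called separately in each stress, 23 genes changed in opposite directions, and the ones given here were picked after their values were seen. RGI1 (3.49 in sorbitol, -2.52 in glucose), MTH1, HXT4 (1.34, -3.57) and the invertase gene SUC2 (1.63, -1.15) were among 8 that rose in sorbitol and fell in glucose. NCW2 (-0.96 in sorbitol, 2.26 in glucose), YPS3 (-1.33, 1.38) and CHS1 (-0.70, 1.64) were among 15 that fell in sorbitol and rose in glucose. Without sorbitol replicate 1, RGI1 and YPS3 lay at 2.01 and -0.86 in sorbitol. Their own difference did not pass, with adjusted p values of 0.126 for NCW2 and 0.131 for RGI1.

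As whole lists, mitochondrial ribosomal proteins, with a median difference of -0.61 (camera, adjusted p = 1.25e-08), cytosolic ribosomal proteins at -0.55 (adjusted p = 2.32e-06) and ribosome biogenesis at -0.63 (adjusted p = 0.00174) were lower in glucose than in sorbitol, each with an adjusted p = 0.892 with an estimated correlation. So were general stress genes at -1.08 (adjusted p = 0.00145), trehalose and glycogen at -1.11 (adjusted p = 0.00145) and glucose-repressed carbon genes at -0.63 (adjusted p = 0.0366), also with an adjusted p = 0.892 each with an estimated correlation. The general stress list and the trehalose and glycogen list share genes. The proteasome at 0.60 (adjusted p = 3.33e-07), the cell wall at 0.52 (adjusted p = 4.73e-05), ergosterol synthesis at 0.33 (adjusted p = 0.00075) and HOG pathway components at 0.55 (adjusted p = 0.00145) were higher, again with an adjusted p = 0.892 each with an estimated correlation. Over all genes, limma called 0 members of these 10 lists. Adjusted over the list alone, 11 cell wall genes were higher and 1 lower, and 8 glucose-repressed genes, 5 trehalose and glycogen genes, 2 mitochondrial ribosomal protein genes and 1 general stress gene were lower. The other 5 lists had 0, with 24 cytosolic ribosomal protein, 9 ribosome biogenesis, 12 proteasome, 9 ergosterol and 8 HOG pathway genes at an unadjusted p under 0.05. Among the members, the glycogen phosphorylase gene GPH1 lay at -3.44, the glycogen synthase gene GSY1 at -3.32, and PBS2, which encodes the kinase that activates Hog1, at 1.39. Without sorbitol replicate 1 the general stress (adjusted p = 0.686), trehalose and glycogen (adjusted p = 0.127) and glucose-repressed lists (adjusted p = 0.636) no longer passed. The glucose-repressed list also missed camera's threshold without glucose replicate 1 (median -0.40), with median centring (-0.70, adjusted p = 0.0803) and with scaled arrays (-0.11, adjusted p = 0.107). Ergosterol synthesis missed it with median centring (0.21, adjusted p = 0.0542). Without glucose replicate 2 the cytosolic ribosomal protein and ribosome biogenesis lists had medians of -0.13 and -0.25 and no longer passed. Ribosome biogenesis lay at 0.20, in the opposite direction, without sorbitol replicate 2. The median of ribosome biogenesis was -1.61 without sorbitol replicate 1 and -1.02 without glucose replicate 1, where cytosolic ribosomal proteins lay at -1.07. Without sorbitol replicate 2 the medians were -1.91 for general stress, -2.01 for trehalose and glycogen, -1.09 for glucose-repressed genes and 0.62 for ergosterol synthesis, and without glucose replicate 2 0.50 for ergosterol synthesis and 0.91 for the cell wall. Scaled arrays gave -0.56 for general stress and -0.98 for ribosome biogenesis, and median centring 0.34 for the proteasome.

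The other 15 lists did not pass in the difference. The respiratory chain had a median of -0.35, glycolysis and fermentation -0.49, the TCA cycle -0.14, the phosphate regulon -0.41, alpha-cell and meiosis markers -0.41 and RNA polymerase subunits -0.36. Sulfur and methionine genes had -0.27, oxidative defence -0.21, the mating response -0.19, histones and S phase 0.24 and glycerol genes 0.19. The respiratory chain passed, downward, with processed signals (adjusted p = 0.0487) and with median centring (0.0135), and RNA polymerase subunits with scaled arrays (0.00906). Without sorbitol replicate 1, RNA polymerase subunits (adjusted p = 0.000244) and the phosphate regulon (0.000545) passed downward and glycerol genes (0.0446) upward. Without sorbitol replicate 2, the respiratory chain (adjusted p = 4.62e-08), glycolysis (0.00175), the TCA cycle (0.00203), oxidative defence (0.00607) and alpha-cell and meiosis markers (0.0328) passed downward, and amino acid biosynthesis (0.00423) and histones and S phase (0.0328) upward. Without glucose replicate 1, glycolysis (adjusted p = 0.00075), the respiratory chain (0.0153) and RNA polymerase subunits (0.0257) passed downward and chaperones (0.0413) upward. Without glucose replicate 2, sulfur and methionine (adjusted p = 0.000287) and the phosphate regulon (0.0304) passed downward. Hexose transporters and sensors had a median of 0.06 but a mean of -1.02 and a downward direction in camera, 6 members lower and 2 higher when adjusted over the list alone, with HXT7 and MTH1 lowest and HXT9 (1.19) and HXT1 highest. Median and mean also had opposite signs for amino acid biosynthesis (0.05 and -0.02), heat shock chaperones (0.08 and -0.12) and the iron regulon (0.13 and -0.04), all upward in camera.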

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

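Tests chosen only after the result was seen were those on the E1A control spots, on leaving out sorbitol replicate 1 and on dye orientation, whereas those on the unstressed channels and on loess had been fixed before.

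In the test of the difference between the stresses, 10 lists passed by camera (adjusted p under 0.05), and each had an adjusted p of 0.892 with an estimated correlation. Median log2 differences, glucose minus sorbitol, were -1.08 for general stress genes, -1.11 for trehalose and glycogen, -0.63 for glucose-repressed carbon genes, -0.55 for cytosolic ribosomal proteins, -0.63 for ribosome biogenesis and -0.61 for mitochondrial ribosomal proteins. Higher in glucose were HOG pathway components (0.55), the proteasome (0.60), the cell wall (0.52) and ergosterol synthesis (0.33). Without sorbitol replicate 2 ribosome biogenesis lay at 0.20 and passed in that direction (adjusted p = 0.0328). Lists that no longer passed were ribosome biogenesis (adjusted p = 0.283) and cytosolic ribosomal proteins (adjusted p = 0.584) without glucose replicate 2, glucose-repressed genes without glucose replicate 1 (adjusted p = 0.0779), and the latter (adjusted p = 0.636), general stress genes (adjusted p = 0.686) and trehalose and glycogen (adjusted p = 0.127) without sorbitol replicate 1. In control spots that the comparisons did not use, the median gene lay at -1.36 relative to the E1A spots in sorbitol and at 0.48 in glucose.

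The first pattern is the difference between the stresses in its 20 named genes, such as HXT4 and RGI1, none of which passed the test, and in its 10 lists. If the unstressed cultures of the sets had differed, the unstressed channels would carry most of it, and they carried a median of 15.2% (quartiles 12.3% and 28.9%) over the genes and of 21.2% (20.0% and 30.0%) over the lists, which argues against that source as the whole cause. Genes ranged from 0.7% (YPS3) to 45.1% (HXK1), and RGI1 lay at 34.8%, with an unstressed difference of 2.09 log2 units. Lists ranged from 8.7% (cytosolic ribosomal proteins) to 42.2% (general stress genes). For such genes and lists the unstressed channels may carry a sizeable part. Whether the 20 genes rest on sorbitol replicate 1 stays open, since they were picked from values that include the arrays left without it. Of the 10 lists 7 still passed in the same direction without it, so for the lists as a set that array stays open as a source: trehalose and glycogen lost its call with 57.8% of its median difference left, and general stress and glucose-repressed genes with 17.3% and 18.3%, a difference that may rest mainly on that array. A different response to the sugar and to the sugar alcohol stays open and was not tested apart from the cultures each stress was applied to. No glucose content was recorded for the sorbitol medium, so an effect of the added compound cannot be told apart from one of the glucose level.

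A second pattern is the wider spread of log2 ratios on sorbitol replicate 1, 1.53 times that on replicate 2. With median centring in place of loess the ratio of SDs was 1.42, which argues against loess as the cause. A wider scale of the whole array would widen the E1A spots too, and their ratio was 1.08, which argues against it. Dye orientation was the same in the glucose pair, where the ratio was 0.882, which argues against it as well. A stronger response in that culture, a biological difference between replicates, could also widen the ratios and was not tested, as the files hold no other array of that culture.

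The third pattern is the shift of the median gene against the E1A control spots. A dye effect shared by the arrays cancels by design in the mean of both dye orientations, so it adds nothing to either mean shift. The arrays lay at -2.01 and -0.71 in sorbitol and at -0.04 and 0.99 in glucose. With the shared dye effect, estimated from these same 4 values, taken out, they lay at -1.43 and -1.30 and at 0.54 and 0.41. That step leaves each mean as it was and forces the same gap within both pairs, so it is no separate evidence. A dye effect that differs between arrays was not tested. Unequal amounts of control RNA cannot be told apart from a change in messenger RNA per unit of total RNA, since the files give no measure of the amount added. The E1A ratios ranged over 3.07 log2 units on the 4 arrays, against 0.873 for the genes. A lower share of messenger RNA in sorbitol-stressed cells may thus remain as an explanation and was not tested.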

How the results depend on the processing

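Scaling of the arrays and centring on the E1A spots were chosen only after the data had been seen; the other alternatives were fixed before. For single genes, 1318 of 1540 values under the alternatives kept direction and side of the threshold, 130 lost and 79 gained a call and 13 turned direction. For lists, 718 of 900 kept both, 103 lost and 43 gained a call and 36 turned direction. These totals include values that could not change, such as the 88 gene values under quantile normalization of average intensities. Directions in a stress also could not turn when an array of the other stress was left out. The shares kept thus overstate how little depends on the processing. Between Agilent's processed signals, no background subtraction, offset 0, median centring, the filters, outlier spots kept, averaged probes, trend with robust prior and the authors' table, limma called 2262 to 2600 genes in sorbitol, 1899 to 2184 in glucose and 0 in the difference (1065 to 1273 at an unadjusted p under 0.05). Quantile normalization of average intensities left the ratios as they were by construction. Signal over background limited little, since 49 genes were left out as dim.

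With a replicate block limma called 2124, 1747 and 0 genes (1188 at an unadjusted p under 0.05), and the test of hexose transporters in glucose turned downward (median 0.16). In the difference the block passed 14 lists against 10, adding glycolysis (adjusted p = 0.038), the respiratory chain (0.022), the phosphate regulon (0.038) and histones and S phase (0.038). In sorbitol it added glycolysis (0.0139) and the TCA cycle (0.0386), and PHO84 in sorbitol (0.0216) and HOR7 in glucose (0.0321) also passed. The same replicate number in the sorbitol and glucose sets gave correlations of 0.0151 after removal of each stress's mean, so the numbers were taken as shared in name only, and the block equals a dye term. A block for slide or scan was not run because all arrays shared 1 of each.

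On its own 2 arrays, each stress gave 0 genes in sorbitol (2484 at an unadjusted p under 0.05), 3214 in glucose and therefore 0 in both. The spread then came from each stress's own pair, and replicates correlated at 0.860 in sorbitol and 0.906 in glucose. The cause of the counts within each stress was not tested. With a minimum of 2-fold the counts were 1614 in sorbitol and 817 in both, by construction. Scaled arrays gave 56 genes in the difference, for which the cause was not tested, and centring on the E1A spots gave 5053 in sorbitol, 5241 in the difference and 758 in both, by the size of its shift. Those counts leave out the spread of the E1A spots between arrays. Camera with an estimated correlation passed 0 lists in sorbitol, 0 in glucose and 0 in the difference, also 0 at an unadjusted p under 0.05, with lowest adjusted p of 0.712, 0.814 and 0.892. Tested for moves in 1 direction, fry passed 0, 0 and 0 lists (6, 6 and 1 at an unadjusted p under 0.05), and for changes in either direction 18, 20 and 5 lists. Both tools rested on 2 residual degrees of freedom, so a list that missed the threshold was not shown to be unchanged. The cause was not tested for either tool.

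Directions turned as follows, and the cause was not tested. With processed signals, the chaperone difference was -0.18. With median centring, SOR1 in sorbitol was 0.016 and the GPD1 difference -0.053, and list medians were, for glycolysis, -0.39 in sorbitol and -0.90 in glucose, and in glucose -0.010 for the respiratory chain, -0.11 for the cell wall and -0.24 for ergosterol, with differences of -0.091 for amino acid biosynthesis and -0.23 for chaperones. By fry the direction of the test turned for hexose transporters in glucose (median 0.16) and for the differences of glycerol genes (0.19), amino acid biosynthesis (0.049), oxidative defence (-0.21) and the iron regulon (0.13). With scaled arrays the differences were 0.42 for STL1, 0.41 for HSP12 and -0.093 for amino acid biosynthesis.

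When 1 array was left out, the lone array of that stress was assumed to vary like the pair of the other. Leaving out either glucose array left 0 genes called by limma in every comparison, where the spread came from the sorbitol pair alone (2484 genes in sorbitol, 1524 and 1008 in glucose and 420 and 414 in the difference at an unadjusted p under 0.05). Over the 4 arrays left out in turn, counts ranged from 0 to 3203 genes in sorbitol, 0 to 3214 in glucose, 0 to 814 in the difference and 0 to 2136 in both. The correlation of the responses ranged from 0.674 to 0.780, and the number of lists in the difference from 10 to 17. Gene differences that turned direction ranged from -0.67 to 1.64 for GPD1, -0.45 to 1.56 for GPP2, -1.15 to 0.24 for STL1, -1.96 to 0.60 for HSP12, -1.70 to 0.15 for CTT1 and -2.77 to 1.17 for HOR7. List medians ranged from -0.073 to 0.21 for the mating response in sorbitol. In glucose they ranged from -0.16 to 0.75 for glycolysis, -0.055 to 0.43 for hexose transporters, -0.57 to 0.22 for sulfur and methionine and -0.32 to 0.084 for the iron regulon. In the difference they ranged from -0.38 to 0.24 for glycerol genes, -0.85 to 0.15 for glycolysis, -0.58 to 0.11 for the TCA cycle, -1.06 to 0.075 for the respiratory chain, -1.61 to 0.20 for ribosome biogenesis, -0.77 to 0.0031 for RNA polymerase subunits and -0.93 to 0.090 for the phosphate regulon. They also ranged from -0.62 to -0.0058 for sulfur and methionine, -0.24 to 0.27 for amino acid biosynthesis, -0.23 to 0.33 for chaperones, -0.77 to 0.14 for oxidative defence and -0.11 to 0.31 for the iron regulon.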

Other observations

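The genes below were picked after their values were seen, and the scaling of the arrays was an alternative added after seeing the data. The fixed cell wall list had a median of 0.52 in glucose (camera, adjusted p = 0.0168, or adjusted p = 0.814 with an estimated correlation), and -0.11 with median centring (adjusted p = 0.861). The kinase gene SLT2 rose in glucose, by 1.75 ± 0.18, the yapsin gene YPS1 by 1.29 ± 0.20, the glucan synthase gene GSC2 by 1.75 ± 0.18 and PRM5 by 1.01 ± 0.18. In sorbitol SLT2 (-0.35), YPS1 (-0.61), GSC2 (0.56) and PRM5 (-0.46) did not pass. PST1, a cell wall protein gene, fell in sorbitol, at -1.14 ± 0.28, and lay at 0.97 in glucose without passing. With the 4 arrays scaled to the same median absolute log ratio, 56 genes passed in the difference, 17 higher and 39 lower in glucose, and 16 of the 20 genes named for the difference were among them. The higher ones then included NCW2, CRH1, YPS3, CHS1, SLT2 and YPS1, and in the unscaled data none of these differences passed (limma, adjusted p = 0.131 for SLT2).

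The fixed mating response list did not pass in glucose (camera, adjusted p = 0.675), with 5 genes up and 7 down of 26. The a-factor gene MFA2 fell in glucose, at -2.64 ± 0.33, as did the agglutinin subunit gene AGA2, at -2.09 ± 0.23, and the alpha-factor receptor gene STE2, at -1.63 ± 0.34. In sorbitol MFA2 (-0.55), AGA2 (-0.10) and STE2 (-0.35) did not pass. The difference itself did not pass for any of the 3 (adjusted p = 0.141, 0.131 and 0.233), although AGA2 passed with scaled arrays at -2.08. HXT2, a glucose transporter gene of higher affinity, fell in glucose, at -3.38 ± 0.21, and the galactose permease gene GAL2 rose in sorbitol, by 3.35 ± 0.33, measured against an unstressed signal that was well above background on only 1 of the 2 sorbitol arrays. GLG1, which primes glycogen synthesis, rose in sorbitol, by 1.72 ± 0.27, and lay at -0.79 in glucose without passing.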
